A study of Caenorhabditis elegans with 12 samples.

How the data were processed

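Hermaphrodites of the Bristol N2 strain of the nematode Caenorhabditis elegans were exposed from the L4 larval stage to methyl parathion, an organophosphate insecticide that inhibits acetylcholinesterase, or to solvent alone, per the labels' protocols. The concentrations were 2.7 and 27 µM and the exposures lasted 24 or 48 h, which with the solvent controls makes 6 groups of 2 arrays, 12 arrays in all. Total RNA was extracted with a column kit and treated with DNase, per the labels' protocols. It was then labelled with Cy3 from an oligo-dT primer and hybridised to a custom Agilent array, per the labels' protocols. The labels give no source culture for a replicate, so a p-value here measures the spread between these samples and not between cultures known to be separate.

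For each array there was 1 scanner file, in which the signal of a spot is an intensity after background subtraction and detrending, per the file headers. That step was done with Agilent Feature Extraction 11.5.1.1, per the file headers. The deposited value table holds log2 signal minus the 75th percentile of each array, with no centring per gene, which was worked out by computing the same quantity from the intensities. The recomputed value lay within 0.01 of the deposited log2 value for 94.6 to 96.7% of probes, depending on the array, and the array medians of the deposited table ran from -3.39 to -2.82. The header cell for the genome build names another organism's assembly, so coordinates were not used.

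The scanner intensities were the starting point. Each array has 62976 spots, 61657 of them not controls. Spots with an outlier flag, 344 to 434 an array, were left out, and the spots of a probe were averaged on the log2 scale. Of 32935 gene probes, 59 had no spot left on at least 1 array, which left 32876. From each probe's log2 value the 75th percentile of its array over gene probes was subtracted. Probes were joined to gene names through a RefSeq table of the WBcel235 assembly, used for names alone: 27288 matched by accession and 4217 by name, 95.8% together, while 383 kept the name in the file and 988 the accession. A probe was tested if it was well above background on both arrays of at least 1 group, which kept 24776 probes. A gene was represented by its tested probe with the highest mean signal over the 12 arrays, which gave 20214 genes. Probe names mark 11005 probes as cross-hybridising with other transcripts and 21871 as specific, and genes represented by a probe of the first kind are given below as "shared probe".

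All comparisons were made with limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group over the 12 arrays, contrasts, and eBayes with default settings, two-sided, with 6 residual and 2.23 prior degrees of freedom. Within each of the 9 comparisons the p-values were adjusted by the method of Benjamini and Hochberg over the 20214 genes, and a gene was called at an adjusted p under 0.05. Errors after ± are limma standard errors of a log2 change, with 2 arrays in each group. Where a gene was not well above background on any array of its dimmer group, the fold is a lower bound. It was computed with each dim array set to the lowest level at which a probe was well above background on that array, or left at the gene's own level where that was higher, and is written "at least". A log2 change printed beside such a fold is the fitted value, which is not a measured size. Genes were ranked by the fitted value, so the rank of a gene with a lower bound is not measured. Gene lists were tested with limma's camera with a preset correlation of 0.01, for 43 lists in 9 comparisons, with 1 adjustment over the 387 tests. The same test with a correlation estimated from the arrays is given beside each call, and fry was run as well. Lists, comparisons, tests and naming rule were fixed before the data were examined. The other software was R's jsonlite 2.0.0 and data.table (1.17.8), python 3.11.15 and matplotlib 3.10.9.

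Genes were named by a rule. It takes ace-1 to ace-4 in each exposure comparison whatever their p. It takes the 8 largest rises and 8 largest falls in each comparison of an exposed group with its control, and the 5 largest of each in the other comparisons, among called genes with a lettered symbol whose exposed arrays both lay on the same side of both arrays of the other group. It takes up to 4 members with the smallest p from each list called, and up to 4 called members of the lists of acetylcholine handling, cytochrome P450, UDP-glucuronosyltransferase and glutathione S-transferase genes. The probe for ace-4 was not well above background on any array and was not tested.

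The steps were tested on simulated data with 200 genes changed among the 20214. The 78 ribosomal protein genes were also shifted slightly and were left out of the false calls. Noise was drawn for each gene on its own from the fitted spread, without correlation between genes or differences between whole arrays. Of genes changed 2-fold, 66% were called in the run for 2.7 µM at 24 h and 65% for 27 µM at 24 h. The share was 65% for 2.7 µM at 48 h and 69% for 27 µM at 48 h. Of genes changed 4-fold the shares were 97, 97, 91 and 91% in the same order, with 8, 12, 6 and 13 false calls. The runs differ by the random draw alone, and their shares need not hold for these arrays.

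The slide and the scan split the arrays as time does: all 24 h arrays are on 1 slide and all 48 h arrays on the other. Comparisons between exposures lie within 1 slide, and a fit to the arrays of 1 time point alone gives the value within a slide. Replicate numbers were not used to pair arrays. The alternatives tried were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, a filter asking for signal above background on all 12 arrays, the mean of a gene's probes, a block for replicate number, eBayes with a trend, the deposited value table, a minimum of 2-fold, a separate fit per time point, and leaving out each array in turn. An estimated correlation was the alternative for the list tests. Added after the data had been seen were leaving out cross-hybridising probes, the list tests within a slide, and leaving out arrays for the overlap between concentrations. Groups of 2 cannot be split further, so no other groupings of the samples were tried.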

Results

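Gene expression was measured in whole C. elegans on 12 single-colour arrays, 2 for each of 6 groups: solvent control, 2.7 µM and 27 µM methyl parathion, each after 24 h and after 48 h. The series compares how organisms respond to environmental agents, and here the questions are which transcripts an acetylcholinesterase inhibitor changes, at which concentration and when. Between 67.9 and 74.8% of probes were well above background on an array, and 0 spots were saturated. The 75th percentile of the signal was 1019 to 1225 intensity units on the 24 h arrays and 397 to 698 on the 48 h arrays, lowest for replicate 1 of 27 µM at 48 h. The number of arrays limits the precision: the median standard error of a log2 change was 0.15 in comparisons of 2 groups. Relative to the 75th percentile, 6 spike-in transcripts added in fixed amounts also differed within a slide. Their mean level for control, 2.7 and 27 µM was 1.41, 1.26 and 1.12 at 24 h (SD 0.13, 0.19 and 0.14, n = 2). At 48 h it was 3.13, 2.88 and 3.23 (SD 0.21, 0.05 and 0.15). Small changes and list medians given below are relative to that percentile.

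After 24 h at 2.7 µM, cytochrome P450 genes were among the largest rises. The level of cyp-35A2 went from 0.26 ± 0.06 in the controls to 2.34 ± 0.20 (log2 signal minus the array's 75th percentile, SD, n = 2), a 4.24-fold rise. The small heat shock gene hsp-16.2 rose 3.68-fold and the desaturase gene fat-5 2.93-fold. In all, 249 genes were called, 137 of them higher.

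Of the 69 P450 genes, 13 rose, 5 fell and 51 were not called (19 and 7 adjusted over the list alone; camera adjusted p = 0.0048, adjusted p = 0.543 with an estimated correlation). Among those that rose, cyp-35A4 was at least 6.65-fold higher (fitted log2 change 3.19 ± 0.46, adjusted p = 0.0243), cyp-35A3 at least 4.04-fold, cyp-35A1 at least 3.06-fold and cyp-35C1 5.91-fold (2.56 ± 0.18, adjusted p = 0.00288). The rise of cyp-25A3 was 2.87-fold. The 5 that fell included cyp-34A2, at 3.85-fold lower (-1.94 ± 0.28), and cyp-33B1, at 3.37-fold lower (-1.75 ± 0.12). The other 3, named here after their values were seen, were cyp-34A1, cyp-33C3 and cyp-33C7. Of 64 UDP-glucuronosyltransferase genes, which attach sugars to foreign compounds, 6 rose and 1, ugt-4 (shared probe, named after its value was seen), fell (14 and 3 adjusted over the list alone; adjusted p = 0.0111, adjusted p = 0.486 with an estimated correlation). They included ugt-37 (2.75-fold), ugt-18 (2.59-fold), ugt-41 (2.43-fold, shared probe) and ugt-22 (2.39-fold). The glucuronosyltransferase list lost its call without control replicate 1 (adjusted p = 0.0768) and without 2.7 µM replicate 2 (0.121). None of the 44 glutathione S-transferase genes was called, and 5 were higher adjusted over the list alone.

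Of 14 small and inducible heat shock genes, 6 rose, 6 also adjusted over the list alone (adjusted p = 0.000469, adjusted p = 0.614 with an estimated correlation). The chaperone gene hsp-16.2 rose 3.68-fold (1.88 ± 0.27, adjusted p = 0.0243), and hsp-16.41, hsp-16.11 and hsp-16.49 rose by 1.55, 1.5 and 1.27 on the log2 scale, all 3 through shared probes. Without shared probes the list was not called (median -0.017 in place of 0.47, adjusted p = 0.314). Of 22 fatty acid synthesis genes 3 rose (6 adjusted over the list alone): the desaturase genes fat-5 (2.93-fold) and fat-6 (2.32-fold, shared probe) and the elongase gene elo-2 (1.73-fold), with a list adjusted p = 0.00018 and adjusted p = 0.486 with an estimated correlation. Also among the largest rises were ech-9, an enoyl-CoA hydratase gene of fatty acid breakdown (6.99-fold), and spp-12, a saposin-like antimicrobial gene (5.77-fold). They were followed by nas-10, a secreted protease gene (4.91-fold, shared probe), and cnc-1, an antimicrobial caenacin gene (4.66-fold). The largest falls, besides those above, were in vmo-1 (3.93-fold, -1.97 ± 0.26), nhr-27 (at least 3.01-fold, shared probe) and str-45 (at least 2.75-fold). Next came sru-28 (at least 2.73-fold), npr-33 (at least 2.24-fold) and zig-13 (log2 change -1.65, above background on 1 of 2 exposed arrays).

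None of the 10 genes of the acetylcholine handling list, which also holds paraoxonase-like (poml) genes, was called after 24 h at 2.7 µM. The acetylcholinesterase genes ace-1 and ace-2 both had log2 changes of 0.03 (± 0.16 each, adjusted p = 0.948 and 0.944), and ace-3 changed by -0.25 ± 0.18 (adjusted p = 0.561). The 34 acetylcholine receptor genes had a median log2 change of -0.15, with 0 called over all genes and 1 lower adjusted over the list alone (adjusted p = 0.000966, adjusted p = 0.486 with an estimated correlation). The list was not called at 27 µM and 24 h (-0.063, adjusted p = 0.426) or at 2.7 and 27 µM after 48 h (0.042 and 0.11, adjusted p = 0.609 and 0.397). The count for this comparison rests on few arrays: it was 83 without control replicate 1, 153 without control replicate 2, 38 without 2.7 µM replicate 1 and 147 without 2.7 µM replicate 2. Limma on the 24 h arrays alone called 0 genes, with 2583 at an unadjusted p under 0.05. Of the genes named by the rule, cyp-35A2, cyp-35C1, cyp-25A3, cyp-33B1, ugt-18, ugt-22, ugt-37, nhr-27 and zig-13 were called without any 1 of the 4 arrays, and the others reached adjusted p-values of up to 0.153 without 1 of them.

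After 24 h at 27 µM the P450 genes cyp-35A2 and cyp-35C1 and antimicrobial genes such as cnc-1 were among the largest rises. The level of cyp-35A2 was 4.03 ± 0.10, a 13.7-fold rise over the controls, and that of cnc-1 went from -6.43 in the controls to 0.01, an 86.9-fold rise. The aldolase gene aldo-2 fell 1.69-fold. In all, 2250 genes were called, 1187 higher and 1063 lower, 11.1% of those tested.

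Of the 69 P450 genes, 21 rose and 9 fell after 24 h at 27 µM (26 and 14 adjusted over the list alone; adjusted p = 0.0185, adjusted p = 0.597 with an estimated correlation). The log2 change of cyp-35A3 was at least 6.89 (adjusted p = 5.4e-05), and cyp-35A4 was at least 95.9-fold higher. The rise was 56.3-fold for cyp-35C1 (5.81 ± 0.18, adjusted p = 9.87e-06), at least 28-fold for cyp-35A1 and 3.74-fold for cyp-34A10. The P450 list was not called when only probes above background on all 12 arrays were kept (adjusted p = 0.153). Of the 64 glucuronosyltransferase genes 15 rose and 6 fell, and the list was not called (21 and 12 adjusted over the list alone; adjusted p = 0.2). Among them ugt-25 rose 5.93-fold (2.57 ± 0.15), ugt-22 4.89-fold, ugt-41 4.61-fold (shared probe) and ugt-37 3.72-fold. Of the 44 glutathione S-transferase genes 4 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.575). The named ones were gst-9 (2.29-fold higher), gst-24 (1.97-fold higher), gst-8 (log2 change 1.35, above background on 1 of 2 control arrays) and gst-34 (2.64-fold lower).

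Of 93 lysozyme and antimicrobial peptide genes, 32 rose and 13 fell (41 and 15 adjusted over the list alone; adjusted p = 8.24e-05, adjusted p = 0.721 with an estimated correlation). The largest rises were in fip-1, a fungus-induced gene (at least 73.7-fold, fitted 6.95 ± 0.32), cnc-1 (6.44 ± 0.26, adjusted p = 3.53e-05) and cnc-6 (at least 28.8-fold, fitted 5.65 ± 0.39), and spp-29 fell 4.51-fold. The protease gene nas-10 rose 111-fold (shared probe). Of 56 transthyretin-like genes, which encode secreted proteins, 17 rose and 4 fell (19 and 6 adjusted over the list alone; adjusted p = 0.00444, adjusted p = 0.721 with an estimated correlation). They include ttr-30 (4.59-fold higher), ttr-59 (3.35-fold), ttr-6 (2.6-fold) and ttr-20 (2.46-fold). Of 14 small heat shock genes 8 rose and 1, hsp-12.1 (shared probe, named after its value was seen), fell, with the same counts adjusted over the list alone (adjusted p = 0.0123, adjusted p = 0.721 with an estimated correlation). Without shared probes that list's median was -0.011 in place of 0.835 (adjusted p = 0.471). The rise was 3.68-fold in hsp-43 (shared probe) and 2.99-fold in hsp-16.2 (1.58 ± 0.27). Through shared probes, hsp-16.41 and hsp-16.49 rose by 1.23 and 1.04 on the log2 scale.

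**Figure D1:**
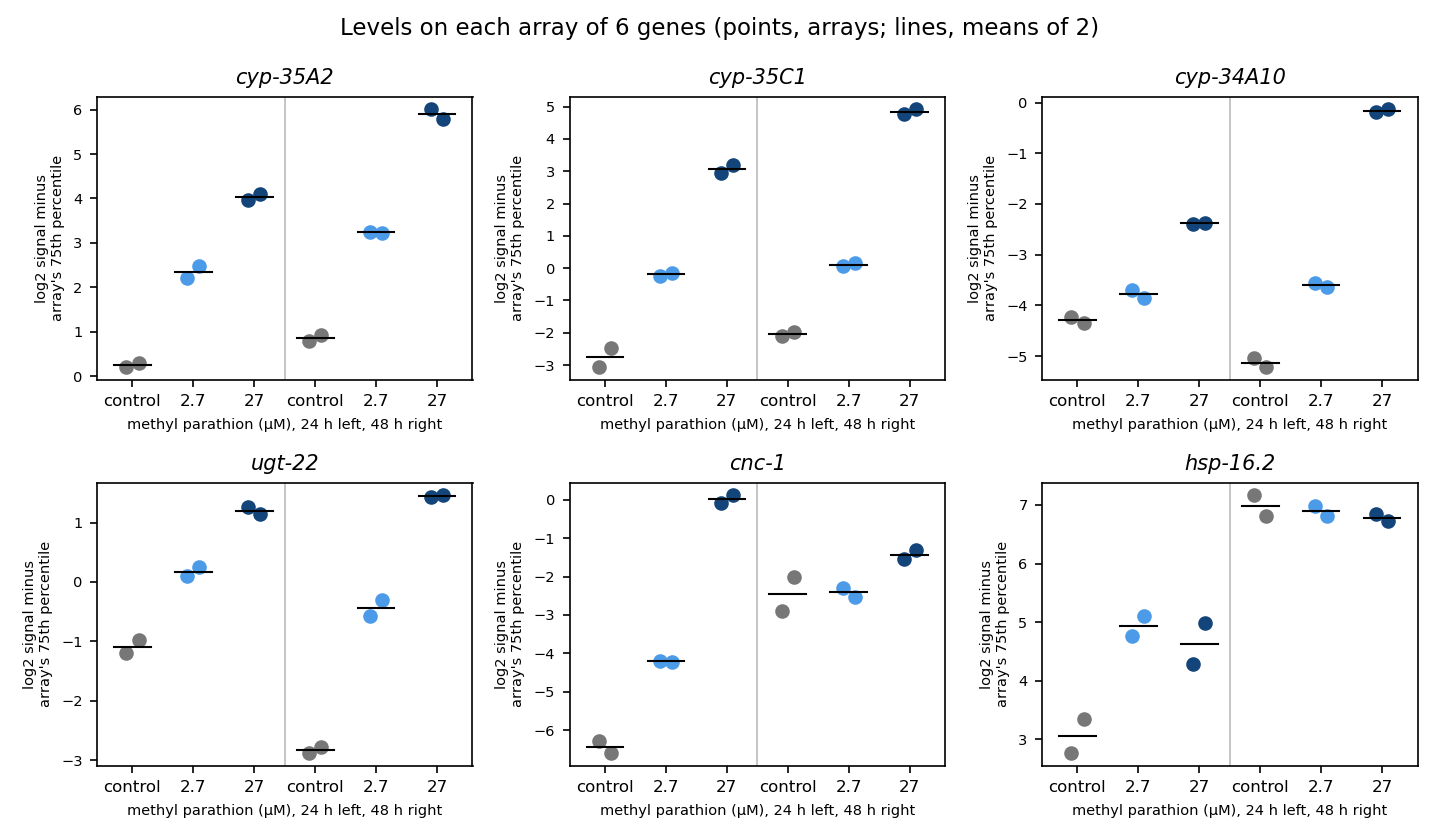
Levels of 6 genes in each array (points) and group means of 2 arrays (lines), as log2 signal minus the array's 75th percentile (vertical axis), for control, 2.7 µM and 27 µM (horizontal axis) after 24 h on the left of each panel and 48 h on the right. From control to 27 µM the mean level of cyp-35A2 goes from 0.26 to 4.03 at 24 h and from 0.85 to 5.90 at 48 h, and that of cnc-1 from -6.43 to 0.01 and from -2.46 to -1.43.

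Of 43 genes of glycolysis and the citrate cycle, 4 fell and 0 rose after 24 h at 27 µM (adjusted p = 9.86e-05, adjusted p = 0.486 with an estimated correlation). They are aldo-2, an aldolase gene (1.69-fold, -0.76 ± 0.11), idh-2 (-0.71), pyk-2 (-0.63, shared probe) and aldo-1 (-0.44). Of 53 respiratory chain genes 5 fell and 0 rose (adjusted p = 0.000641, adjusted p = 0.651 with an estimated correlation). Their log2 changes were -0.47 for gas-1, -0.45 for asb-2, -0.41 for cox-4 and -0.37 for nduf-5, and the other was ucr-2.1 (shared probe, named after its value was seen). The spike-in mean went from 1.41 to 1.12 between the same groups, so the size of such small falls depends on the scale used. Of 19 hypoxia and hydrogen sulfide genes 5 fell (1 higher and 9 lower adjusted over the list alone; adjusted p = 0.00524, adjusted p = 0.654 with an estimated correlation). They are the metal transporter gene smf-3 (2.2-fold), phy-2 (-0.75), egl-9 (-0.74, shared probe), cth-1 (-0.57, shared probe) and kynu-1, named after its value was seen. Of the 10 genes of the acetylcholine handling list 3 fell (3 also adjusted over the list alone; adjusted p = 0.00271, adjusted p = 0.569 with an estimated correlation; median -0.356, and -0.251 with adjusted p = 0.0538 without shared probes). All 3 are paraoxonase-like genes, which the list holds beside the acetylcholinesterase genes. On the log2 scale poml-2 fell by 1.15 ± 0.11 (adjusted p = 0.000672), and poml-3 and poml-4 fell by 0.71 and 0.60 through shared probes. The log2 change was 0.00 ± 0.16 for ace-1 (adjusted p = 0.993), -0.03 ± 0.16 for ace-2 (0.938) and -0.43 ± 0.18 for ace-3 (0.164), none called.

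Among the largest falls after 24 h at 27 µM were the lipase gene lipl-4 (4.98-fold, -2.32 ± 0.27, adjusted p = 0.00169), the lectin gene clec-165 (5.4-fold) and pud-4 (4.77-fold). The chitinase-like genes chil-7 and chil-28 were at least 5.06-fold and, through a shared probe, at least 5.24-fold lower. Other large falls were in scl-11 (at least 4.19-fold) and str-45 (at least 3.05-fold). Both large ribosomal RNA probes were lower as well, rrn-2.1 6.41-fold (-2.68 ± 0.63) and rrn-1.2 from a level of -1.61 to -2.71 (shared probe, named after its value was seen, adjusted p = 0.0272). Whether RNA preparation or labelling differed for the 27 µM arrays was not tested, and it remains open for the other changes of this group too. Camera also placed histones lower (0 higher and 4 lower, adjusted p = 2.72e-05, adjusted p = 0.737 with an estimated correlation), with hil-1 2.16-fold lower. Without shared probes the histone median was 0.039 in place of -0.208 (adjusted p = 0.494). Moulting genes were placed lower too, with 2 higher and 5 lower (adjusted p = 0.00158, adjusted p = 0.721 with an estimated correlation). Of these ptr-22 (2.83-fold, shared probe) and ptr-8 rose. Monoamine signalling genes had 3 lower, cat-1, bas-1 and amx-3, all through shared probes (adjusted p = 0.0201, adjusted p = 0.486 with an estimated correlation). That call was lost without shared probes (median -0.234 beside -0.177, adjusted p = 0.059), without control replicate 2 (0.0574) and without 27 µM replicate 1 (0.0547). The number of genes called was 1290 without control replicate 1, 1234 without control replicate 2, 1880 without 27 µM replicate 1 and 1015 without 27 µM replicate 2. Limma on the 24 h arrays alone called 972. Without at least 1 array the calls of rrn-2.1 (adjusted p up to 0.182), hsp-16.2 (0.05), hsp-16.49 (0.0665), idh-2 (0.108), pyk-2 (0.102) and aldo-1 (0.153) were lost. So were those of the 4 respiratory chain genes given with values (up to 0.178), phy-2 (0.128), cth-1 (0.144) and the 3 monoamine genes (up to 0.103).

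After 48 h at 2.7 µM P450 and glucuronosyltransferase genes were again among the largest rises, and more genes fell than rose. Of 569 genes called, 152 were higher and 417 lower. The level of ugt-22 was -2.83 in the controls and -0.44 at 2.7 µM, a 5.25-fold rise, and that of cyp-35A2 rose 5.23-fold. The acetylcholinesterase gene ace-2 fell 1.88-fold.

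Of the 69 P450 genes 11 rose and 2 fell, the latter cyp-33B1 and cyp-13A5 (shared probe), named after their values were seen (14 and 6 adjusted over the list alone; adjusted p = 0.000763, adjusted p = 0.486 with an estimated correlation). The rise was at least 6.76-fold for cyp-35A4 (fitted 3.61 ± 0.46, adjusted p = 0.0092), 4.96-fold for cyp-35A1, 4.44-fold for cyp-35C1 (2.15 ± 0.18, adjusted p = 0.00263) and 2.88-fold for cyp-34A10 (1.52 ± 0.099). It was at least 2.93-fold for cyp-35A3, which was above background on 1 of 2 exposed arrays. Of the 64 glucuronosyltransferase genes 9 rose and 1, ugt-51 (named after its value was seen), fell (14 and 3 adjusted over the list alone; adjusted p = 0.000188, adjusted p = 0.37 with an estimated correlation). The log2 change of ugt-22 was 2.39 ± 0.13 (adjusted p = 0.000453), and ugt-63 was at least 5.35-fold, ugt-37 2.66-fold and ugt-9 2.42-fold (shared probe) higher. None of the 44 glutathione S-transferase genes was called. The neuropeptide gene nlp-76 rose 4.13-fold (2.05 ± 0.12). It is the 1 that rose of 141 neuropeptide and insulin genes, of which 4 fell (2 and 8 adjusted over the list alone; adjusted p = 2e-04, adjusted p = 0.569 with an estimated correlation), among them ins-21 (-1.14), nlp-31 (-0.95) and nlp-9 (-0.50).

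Of the 10 genes of acetylcholine handling ace-2 alone was called after 48 h at 2.7 µM, also adjusted over the list alone (-0.91 ± 0.16, adjusted p = 0.0276; list adjusted p = 0.0094, adjusted p = 0.597 with an estimated correlation). The gene's call was lost without any 1 of the 4 arrays (adjusted p up to 0.149), and the list's call without control replicate 2 (0.0637) or 2.7 µM replicate 2 (0.0553). The log2 change of ace-1 was -0.01 ± 0.16 (adjusted p = 0.99) and that of ace-3, not above background on either exposed array, -0.22 ± 0.18 (0.601). Histones were lower as a list, with 7 of 58 fallen and 32 adjusted over the list alone (adjusted p = 1.17e-14, adjusted p = 0.614 with an estimated correlation). Of the 58, 50 have shared probes, without which the list was not called (median -0.07 in place of -0.328, adjusted p = 0.0983). Of these hil-3, a linker histone gene, fell 2-fold (SE 0.14 on the log2 scale) and his-24 by 1.34 on the log2 scale (shared probe). The 25 pharynx genes had a median log2 change of 0.31 with 0 called (adjusted p = 8.85e-05, adjusted p = 0.651 with an estimated correlation). After 24 h at 2.7 µM their median was -0.253, also with 0 called (adjusted p = 0.000887, adjusted p = 0.721 with an estimated correlation), a call lost without control replicate 2 (-0.11, adjusted p = 0.113) or 2.7 µM replicate 2 (-0.144, 0.0934). The change of the 2.7 µM effect between the times was 0.646 (adjusted p = 5.29e-08, adjusted p = 0.569 with an estimated correlation). The neuronal gene rgef-1 fell 2.17-fold (shared probe), the lysozyme gene lys-3 2.14-fold and the transthyretin-like gene ttr-37 2.1-fold.

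The largest falls after 48 h at 2.7 µM were in the non-coding RNA linc-158 (6.78-fold, -2.76 ± 0.34), the lectin gene clec-9 (4.37-fold, -2.13 ± 0.41), ccm-2 (4.25-fold) and ccar-1 (at least 3.53-fold). They were followed by srtx-1 (at least 2.58-fold), str-135 (at least 2.11-fold), clc-12 (-1.80) and cld-1 (-1.75, shared probe). On 1 of 2 exposed arrays alone linc-158, ccm-2, clc-12 and cld-1 were above background. The count of called genes was 82 without control replicate 1, 105 without control replicate 2, 370 without 2.7 µM replicate 1 and 55 without 2.7 µM replicate 2, and limma on the 48 h arrays alone called 124. The share of called genes that were higher, 26.7%, was 43% after quantile normalization. Of the genes named for this comparison by the rule, ugt-22, ugt-37, cyp-35A2, cyp-35C1, cyp-34A10, nlp-76, srtx-1 and rgef-1 were called without any 1 array.

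After 48 h at 27 µM P450 genes were among the largest rises. The level of cyp-35A2 was 0.85 in the controls and 5.90 at 27 µM, a 33.1-fold rise, and that of cyp-34A10 went from -5.13 to -0.16, a 31.1-fold rise. The collagen genes col-45 and col-164 were among the largest falls, and ace-2 fell 1.72-fold. In all, 1386 genes were called, 747 higher and 639 lower.

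Of the 69 P450 genes 17 rose and 4 fell after 48 h at 27 µM (24 and 6 adjusted over the list alone; adjusted p = 3.72e-06, adjusted p = 0.381 with an estimated correlation). The rises were at least 275-fold for cyp-35A4 (fitted 8.96 ± 0.46, adjusted p = 4.98e-05), at least 145-fold for cyp-35A3, and 118-fold for cyp-35C1 (6.88 ± 0.18, adjusted p = 7.07e-07). They were at least 97.9-fold for cyp-14A3, 65.1-fold for cyp-35A1 and 10.5-fold for cyp-14A2. The 4 that fell, named after their values were seen, were cyp-33B1, cyp-33C3, cyp-33C7 and cyp-13A5 (shared probe). Of the 64 glucuronosyltransferase genes 20 rose and 1, ugt-28 (named after its value was seen), fell (25 and 4 adjusted over the list alone; adjusted p = 1.7e-06, adjusted p = 0.37 with an estimated correlation). Among them ugt-22 rose 19.4-fold (4.28 ± 0.13, adjusted p = 1.34e-06), ugt-9 9.63-fold (shared probe), ugt-33 7.81-fold and ugt-25 6.05-fold. The short-chain dehydrogenase gene dhs-23 rose 38.2-fold (5.26 ± 0.13, adjusted p = 5.18e-07). Of the 44 glutathione S-transferase genes gst-5 (0.70, shared probe) rose and gst-29 (-0.93) and gst-28 (-0.49) fell (1 and 3 adjusted over the list alone; adjusted p = 0.165).

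**Figure D2:**
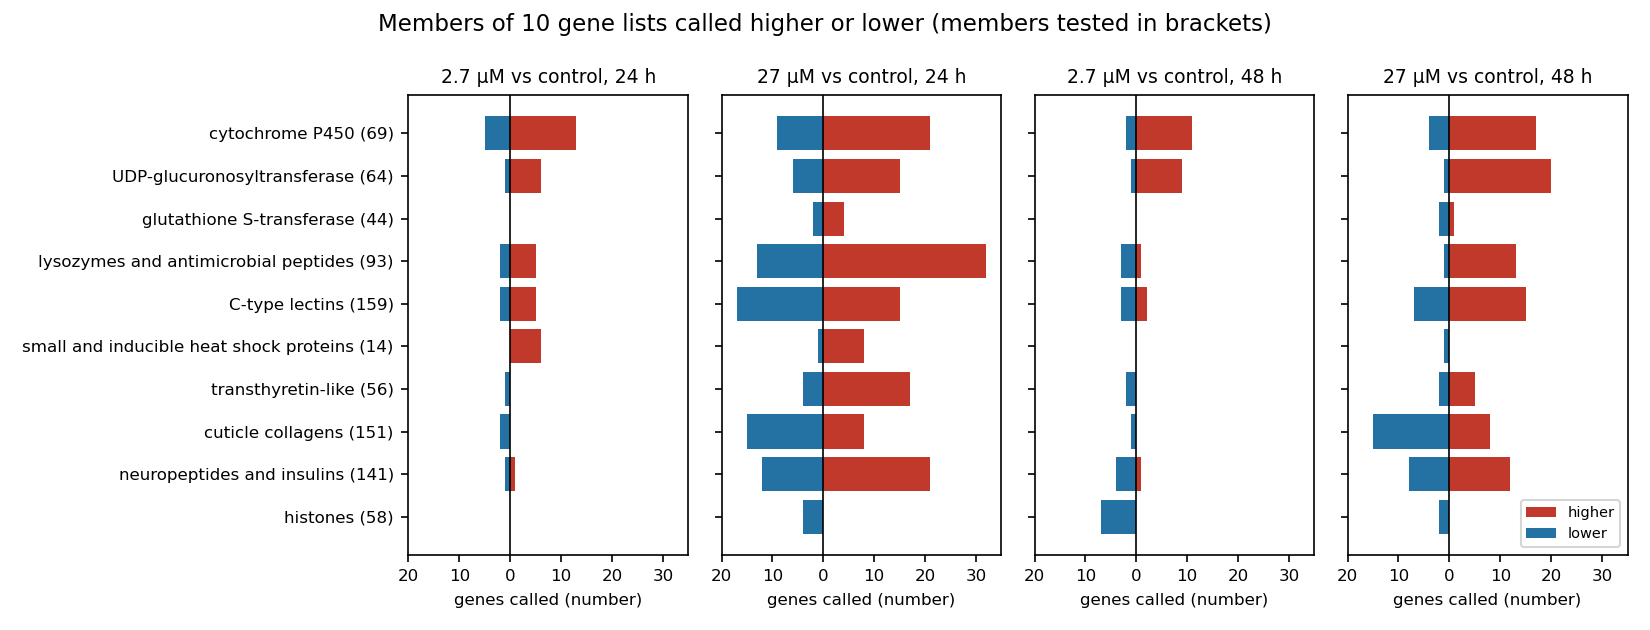
Number of members called higher (red, to the right) and lower (blue, to the left) in each of 10 gene lists (vertical axis) in the 4 comparisons of an exposed group with its control. The cytochrome P450 list has 13, 21, 11 and 17 called higher at 2.7 µM 24 h, 27 µM 24 h, 2.7 µM 48 h and 27 µM 48 h.

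Of 40 genes of beta-oxidation and the fasting response 2 rose and 7 fell after 48 h at 27 µM (3 and 10 adjusted over the list alone; adjusted p = 0.00948, adjusted p = 0.614 with an estimated correlation). Without shared probes its median stayed near, -0.14 beside -0.155, and the call was lost (adjusted p = 0.0717). The carnitine palmitoyltransferase genes cpt-4 and cpt-1 were 2.61-fold (-1.39 ± 0.12) and 2.04-fold lower. The log2 change of ech-6 was -0.80, and ech-9 was 6.14-fold higher. Of 5 vitellogenin genes, which encode yolk proteins, vit-5 and vit-4 rose 2.61-fold and 2.53-fold, both through shared probes (3 higher adjusted over the list alone; adjusted p = 0.0147, adjusted p = 0.721 with an estimated correlation). Glycolysis and citrate cycle genes had 3 lower and 0 higher, pyk-2, mdh-1 and idh-1, all through shared probes (adjusted p = 0.00012, adjusted p = 0.486 with an estimated correlation). Of 21 oxidative stress genes 2 fell (adjusted p = 0.00373, adjusted p = 0.584 with an estimated correlation). Without shared probes the call was lost (adjusted p = 0.0707), with a median of -0.261 beside -0.229. The 2 are the superoxide dismutase gene sod-3 (2.26-fold) and trx-1 (-1.17, shared probe, above background on 1 of 2 exposed arrays). Of 33 body wall muscle genes 4 rose (5 adjusted over the list alone; adjusted p = 0.00282, adjusted p = 0.651 with an estimated correlation). After normexp correction the call was lost (adjusted p = 0.416), with a median of 0.173 beside 0.138. The myosin gene myo-3 rose 1.44-fold, unc-60 by 0.55 on the log2 scale, and mup-2 and ttn-1 by 0.52 and 0.36 through shared probes. Without shared probes the log2 change of ttn-1 was negative, as given below.

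Of 151 cuticle collagen genes 8 rose and 15 fell after 48 h at 27 µM (11 and 18 adjusted over the list alone), and the list was not called (median log2 change -0.15, adjusted p = 0.104). It was called lower with no filter on dim probes (-0.104, adjusted p = 0.00764) and without control replicate 2 (-0.172, 0.0239), and called after normexp correction with a median of 0.001 (2.47e-05). The largest falls of named genes were in col-45 (at least 8.85-fold, fitted -4.17 ± 0.58, adjusted p = 0.006), col-164 (at least 6.44-fold), col-185 (at least 6.11-fold), col-2 (6.35-fold, shared probe) and col-43 (6.3-fold). Others were in scl-13 (at least 9.7-fold), linc-158 (at least 9.37-fold) and the nuclear receptor gene nhr-247 (5.77-fold). Without control replicate 1, control replicate 2, 27 µM replicate 1 or 27 µM replicate 2 the collagen genes called lower numbered 2, 4, 8 and 11. Of these named falls linc-158, col-45 and col-164 were called without any 1 array, and the others reached adjusted p-values of up to 0.209 without 1. The collagens col-45 and col-164 were not called after normexp correction.

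Of the 10 genes of the acetylcholine handling list ace-2 and the paraoxonase-like gene poml-2 fell after 48 h at 27 µM, also adjusted over the list alone (adjusted p = 0.0279, adjusted p = 0.651 with an estimated correlation). On the log2 scale poml-2 fell by 0.67 ± 0.11 (adjusted p = 0.0106) and ace-2 fell by 0.79 ± 0.16 (adjusted p = 0.0262). The list, with a median of -0.201, was not called after normexp correction (-0.039, adjusted p = 0.168) or without shared probes (-0.273, 0.101). Nor was it called without control replicate 2 (-0.154, 0.118) or 27 µM replicate 2 (-0.185, 0.11). The call of ace-2 was lost without either control replicate or 27 µM replicate 2 (adjusted p up to 0.127), and that of poml-2 without 3 of the 4 arrays (up to 0.0778). The log2 change of ace-1 was 0.13 ± 0.16 (adjusted p = 0.705) and that of ace-3, above background on 1 of the 4 arrays, 0.21 ± 0.18 (0.555). The number of genes called was 388 without control replicate 1, 469 without control replicate 2, 613 without 27 µM replicate 1 and 786 without 27 µM replicate 2, and limma on the 48 h arrays alone called 912. The share called higher, 53.9%, was 67.9% after normexp correction, which moved the median of all genes by 0.12. The calls of ech-9 (adjusted p up to 0.0642), ech-6 (0.0779), sod-3 (0.182), and trx-1 (0.196) were lost without at least 1 array. The same holds for the 4 muscle genes (up to 0.214), the 3 glycolysis genes (up to 0.192) and the 3 glutathione S-transferase genes (up to 0.158).

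**Figure D3:**
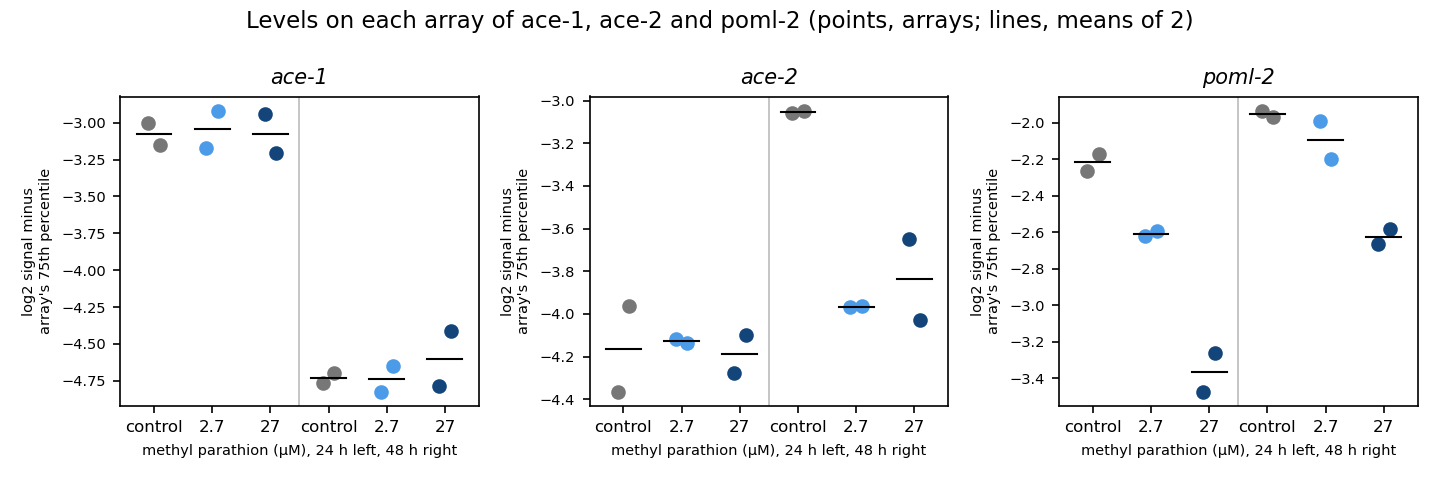
Levels of ace-1, ace-2 and poml-2 in each array (points) and group means of 2 arrays (lines), as log2 signal minus the array's 75th percentile (vertical axis), for control, 2.7 µM and 27 µM (horizontal axis) after 24 h on the left and 48 h on the right. At 48 h the mean level of ace-2 is -3.05 in the controls, -3.97 at 2.7 µM and -3.84 at 27 µM, and at 24 h the 3 means lie between -4.19 and -4.13.

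The higher concentration was also compared with the lower 1 within each time. After 24 h 949 genes differed between 27 and 2.7 µM, 646 of them higher at 27 µM and 303 lower. The largest rises by fitted value were in cnc-6 (at least 25.1-fold, fitted 5.06 ± 0.39), cyp-35A3 (29.4-fold), fip-1 (28.8-fold), nas-10 (22.7-fold, shared probe) and cnc-1 (18.6-fold, adjusted p = 0.00076). The largest falls by fitted value were in srw-112 (at least 1.98-fold, so its rank is not measured), clec-61 (3.88-fold), dhs-26 (2.96-fold), pugs-8 (2.96-fold) and col-179 (2.84-fold). Of 93 antimicrobial genes 24 rose and 6 fell (35 and 12 adjusted over the list alone; adjusted p = 0.00012, adjusted p = 0.723 with an estimated correlation), with fipr-21 3.68-fold higher. Of 56 transthyretin-like genes 17 rose and 1 fell (22 and 3 adjusted over the list alone; adjusted p = 1.5e-07, adjusted p = 0.569 with an estimated correlation). Of 141 neuropeptide and insulin genes 23 rose and 2 fell (30 and 5 adjusted over the list alone; adjusted p = 0.000193, adjusted p = 0.569 with an estimated correlation). Among these nlp-34 was 5.93-fold higher and ins-11 rose by 1.70 ± 0.15 on the log2 scale. The P450 list was not called (13 higher and 5 lower, median -0.09, mean 0.27, adjusted p = 0.533). The paraoxonase-like genes that fell were poml-2, 1.69-fold lower, and poml-3 and poml-4, 1.48-fold each (shared probes; list adjusted p = 0.00924, adjusted p = 0.597 with an estimated correlation; median -0.132, and -0.068 with adjusted p = 0.174 without shared probes). The count was 759 without 2.7 µM replicate 1, 333 without 2.7 µM replicate 2, 742 without 27 µM replicate 1, and 333 without 27 µM replicate 2, and limma on the 24 h arrays alone called 95. The 10 genes with the largest changes were called without any 1 array, while poml-2 was lost without 1 (adjusted p = 0.0567) and poml-3 and poml-4 without 3 (up to 0.11).

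After 48 h 252 genes differed between 27 and 2.7 µM, 215 of them higher at 27 µM. The P450 gene cyp-35C1 was 26.5-fold higher (4.73 ± 0.18, adjusted p = 1.86e-05), cyp-35A4 40.7-fold, cyp-35A3 49.5-fold and cyp-14A3 42.1-fold, the last 2 above background on 1 of 2 arrays at 2.7 µM, and dhs-23 was 15.4-fold higher. Of 69 P450 genes 10 rose and 0 fell (11 and 2 adjusted over the list alone; adjusted p = 8.23e-05, adjusted p = 0.469 with an estimated correlation). Of 64 glucuronosyltransferase genes 9 rose and 0 fell (19 and 3 adjusted over the list alone; adjusted p = 7.36e-05, adjusted p = 0.37 with an estimated correlation), among them ugt-33 6.95-fold. Of 93 antimicrobial genes 11 rose and 0 fell (20 and 0 adjusted over the list alone; adjusted p = 0.000312, adjusted p = 0.737 with an estimated correlation), with fipr-26 6.97-fold and cnc-11 5.28-fold higher. The yolk protein genes vit-4 and vit-5 rose 3-fold and 2.94-fold (shared probes; list adjusted p = 0.00018, adjusted p = 0.597 with an estimated correlation). The largest falls were in nspb-1 to nspb-5, 5 members of 1 gene family measured with shared probes, between 5.88-fold and 6.91-fold. The count was 111 without 2.7 µM replicate 1, 103 without 2.7 µM replicate 2, 79 without 27 µM replicate 1, and 132 without 27 µM replicate 2, and limma on the 48 h arrays alone called 107. The calls of nspb-2 and nspb-3 were lost without 1 array (adjusted p up to 0.0782), and the share called higher, 85.3%, was 73.1% after quantile normalization.

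Both concentrations called the same genes in part. After 24 h, 202 genes were called in the same direction at both, 115 higher and 87 lower, and 1, F19B10.13, in opposite directions (-0.94 at 2.7 µM and 0.96 at 27 µM). After 48 h the count was 396, 121 higher and 275 lower, with ptr-22 (shared probe) opposite (-1.09 and 1.48). Independent lists would share 8 higher and 5.9 lower genes at 24 h and 5.6 and 13.2 at 48 h. In 100 simulations of unchanged groups against the same controls the mean overlap was 0.01 and 0. No gene was changed in those simulations, so they cannot show how large an overlap shared controls give among changed genes. The correlation of the log2 changes across genes, which are not independent replicates, was 0.619 at 24 h and 0.666 at 48 h, beside 0.501 and 0.5 in the simulations, and the covariance was 0.126 and 0.122 beside 0.029 and 0.0289. Part of the excess may come from the shared controls, which with 2 arrays cannot be split. The overlap at 24 h was 64 without control replicate 1, 132 without control replicate 2, 24 without 2.7 µM replicate 1 and 105 without 2.7 µM replicate 2. At 48 h it was 62, 80, 243 and 51 without the like arrays, and 232 without 27 µM replicate 1 and 226 without 27 µM replicate 2.

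Control animals at 48 h differed from those at 24 h in most genes: 16089 were called, 10437 higher and 5652 lower, with a median log2 change over all genes of 0.46. Cuticle collagen genes were higher, with 137 of 151 called higher and 9 lower (median 2.84; adjusted p = 2.65e-08, adjusted p = 0.577 with an estimated correlation). Oocyte genes were lower, with 1 higher and 29 lower of 32 (median -1.76; adjusted p = 4.09e-10, adjusted p = 0.631 with an estimated correlation). This comparison sets 1 slide against the other, and time cannot be told apart from a difference in RNA preparation or labelling. Spike-in transcripts, added in fixed amounts, lay 1.72 higher in log2 units at 48 h relative to the array's 75th percentile, and the ribosomal RNA probes rrn-1.2 (shared probe) and rrn-2.1 were higher by 8.57 and 5.07.

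Beside those differences, the largest rises from 24 to 48 h in the controls were in the collagen genes col-37 (at least 1160-fold, fitted 11.25 ± 1.28), col-40 (at least 387-fold) and col-2 (at least 210-fold). The ground-like gene grl-23 rose at least 438-fold and rrn-1.2 379-fold, and of these 5 genes all but col-37 have shared probes. The largest falls were in col-74 (74.1-fold), the cuticlin genes cut-3 (49.5-fold) and cutl-2 (at least 35.2-fold), meg-2, a germ granule gene (at least 30.8-fold), and ifa-3 (at least 21.9-fold). Of 93 antimicrobial genes 85 rose and 0 fell (adjusted p = 4.73e-08, adjusted p = 0.631 with an estimated correlation), with cnc-8 19.2-fold higher and a log2 change of 4.01 for cnc-2. The heat shock gene hsp-16.2 was 15.3-fold higher, again with spike-in transcripts 1.72 higher. Of 44 glutathione S-transferase genes 39 rose and 0 fell (adjusted p = 0.000469, adjusted p = 0.721 with an estimated correlation), with gst-24 5.21-fold. Of 38 replication genes 2 rose and 32 fell, with mcm-7 10.1-fold lower (adjusted p = 6.69e-10, adjusted p = 0.597 with an estimated correlation). The germline receptor gene glp-1 was 10.5-fold, spn-4 5.82-fold and oma-1 4.68-fold lower, with rrn-2.1 higher by 5.07. Of 5 vitellogenin genes 3 fell, vit-4, vit-5 and vit-6 (shared probes; adjusted p = 0.0346, adjusted p = 0.729 with an estimated correlation, 0.0506 without 24 h control replicate 2 and 0.0512 without 48 h control replicate 1). The share called higher, 64.9%, was 50.8% after quantile normalization, which moved the median of all genes to 0.04.

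The change of each exposure's effect from 24 to 48 h was called for 89 genes at 2.7 µM (29 higher and 60 lower) and 700 genes at 27 µM (367 and 333). A log2 difference common to the arrays of 1 slide cancels in this comparison. A difference between the slides in how signal scales with level would not cancel. The slope of the spike-in fit, per the file headers, did differ. It was 0.9555 to 0.9784 on the 24 h arrays and 0.9132 to 0.9505 on the 48 h arrays. How far this adds to the calls was not tested. The effect of 27 µM on cyp-34A10 grew by 3.06 ± 0.14 (adjusted p = 0.000297) and on ugt-22 by 1.99 ± 0.18, and its effect on cnc-1 fell by 5.41 ± 0.37 (adjusted p = 0.002). Of the genes called at 27 µM at both times 298 were higher and 180 lower at both and 58 went opposite ways, where independent lists would share 43.9 and 33.6. At 2.7 µM the numbers were 26, 18 and 9, with 1 and 2.3 for independent lists. The count at 2.7 µM was 0 without 48 h control replicate 1 or 2 or 48 h 2.7 µM replicate 2 in limma (unadjusted p under 0.05 for 2011, 2123 and 2029 genes). It was 24, 31 and 41 without 24 h control replicate 1, 24 h 2.7 µM replicate 1 and 48 h 2.7 µM replicate 1. At 27 µM it was 382, 340 and 226 without 24 h control replicate 1, 24 h control replicate 2 and 24 h 27 µM replicate 2. It was 173, 200 and 245 without 48 h control replicate 1, 48 h control replicate 2 and 48 h 27 µM replicate 1.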

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

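The tests of RNA preparation, of a smaller germline share and of cross-hybridising probes were chosen after the result was seen; the others were written down before.

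The effect of exposure differed between 24 and 48 h, by a limma test of the difference itself, for 89 genes at 2.7 µM and 700 at 27 µM. At 2.7 µM the log2 effect changed by 2.413 in zig-13, 1.834 in clec-165, 1.708 in nlp-76, 1.541 in glb-34 and 1.524 in chil-23 (the last 2 shared probes). It changed by -3.166 in bath-25, -2.394 in kreg-1, -2.277 in ccm-2, -2.263 in clec-221 and -2.205 in oac-31. A positive change is not always a stronger effect: zig-13 was among the largest falls at 24 h. In zig-13, bath-25 and ccm-2, 1 of the 4 groups compared was above background on 1 of its 2 arrays. Limma called 0 of the 2.7 µM differences without 48 h control replicate 1, 48 h control replicate 2 or 48 h 2.7 µM replicate 2 (2011, 2123 and 2029 genes at an unadjusted p under 0.05), so these rest on those arrays.

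At 27 µM the log2 effect changed by 3.056 in cyp-34A10, by 2.86 in clec-165 and by -5.411 in cnc-1. Since clec-165 was among the largest falls at 24 h, its positive change is not a stronger effect at 48 h. Differences were also called in clec-206, chil-28 (shared probe), str-45, fip-1, cnc-6, col-2 and col-40 (the last 2 shared probes). Their fitted values, 3.407, 2.967, 2.837, -5.529, -4.802, -5.131 and -4.886, are neither measured sizes nor bounds, because at least 1 of the 4 groups compared was not well above background on either array. In clec-206 and str-45 this was so for 3 of the 4. The calls of chil-28 and str-45 were lost without 1 array (adjusted p up to 0.109 and 0.0688). Without 1 array the number called at 27 µM was 382, 340, 514 and 226 for the 24 h arrays (controls, then 27 µM) and 173, 200, 245 and 471 for the 48 h arrays in that order.

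Of 43 lists 17 had a called difference at 27 µM, given by median log2 change. The median of the P450 genes was 0.233 (10 higher and 2 lower, 18 and 5 adjusted over the list alone, adjusted p = 0.486 with an estimated correlation). For the glucuronosyltransferase genes it was 0.263 (8 and 2, 13 and 2 adjusted over the list alone, adjusted p = 0.37 with an estimated correlation), and for the carboxylesterase and lipase genes 0.407 (10 and 1, 14 and 4 adjusted over the list alone, adjusted p = 0.597 with an estimated correlation). Nuclear hormone receptor genes had 0.184 (13 and 2, 24 and 11 adjusted over the list alone, adjusted p = 0.721 with an estimated correlation), not called with no filter on dim probes (adjusted p = 0.0981). Lower were small heat shock genes at -0.748 (0 and 4, 1 and 8 adjusted over the list alone, adjusted p = 0.614 with an estimated correlation). So were antimicrobial genes at -0.319 (4 and 8, 5 and 14 adjusted over the list alone, adjusted p = 0.737 with an estimated correlation) and neuropeptide genes at -0.136 (1 and 3, 2 and 5 adjusted over the list alone, adjusted p = 0.684 with an estimated correlation). These 2 calls were lost without 48 h 27 µM replicate 2 (adjusted p = 0.0563) and without 48 h control replicate 1 (0.0579). The other lists had 2 or fewer members called. Higher were moulting genes at 0.285, muscle genes at 0.223, ribosomal protein genes at 0.232, zygotic genes at 0.269, vitellogenin genes at 0.464 and monoamine genes at 0.152 (adjusted p = 0.651, 0.614, 0.814, 0.486, 0.721 and 0.486 with an estimated correlation). Lower were transthyretin-like genes at -0.211, chaperone genes at -0.115, germline genes at -0.126 and proteasome genes at -0.132 (adjusted p = 0.737, 0.703, 0.805 and 0.779 with an estimated correlation). Of these 10 all but moulting lost the call in some other setting too, the ribosomal genes with a median of -0.017 after quantile normalization (adjusted p = 0.799).

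The most widespread pattern is the difference between the times in the controls, where 16089 genes were called. For genes of like brightness the tables argue against a difference in hybridisation or scan as its source: the SD over 6 spike-in transcripts of their change was 0.13, against 1.37 over 14054 genes. The slope of the spike-in fit did differ between the slides, at 0.9555 to 0.9784 for 24 h and 0.9132 to 0.9505 for 48 h. Genes below a level of -4 are not covered by the test of spike-in changes. The dimmest 5054 genes had a median change of 1.61, and of 0.36 after quantile normalization. For dim genes a difference in hybridisation or scan thus stays open. The tables also argue against a smaller germline share raising all other tissues alike, since the lower quartile of the collagen genes' change lay 0.99 above the higher of the upper quartiles of muscle and pan-neuronal genes. The collagen list was taken for this after its rise was seen. A smaller germline share as part of the pattern stays open: the quartiles were -0.43 to 0.86 for muscle, -0.79 to 0.25 for pan-neuronal, -0.28 to 1.19 for intestine and -2.36 to -0.91 for oocyte genes. A difference in RNA preparation or labelling stays open, because the smaller of the changes of the ribosomal RNA probes was 5.07, beyond the 4.04 that 2.5% of genes pass, and it cannot be told apart from time, which splits the samples in the same way. Exposure began at L4, and both groups of controls were sampled later. Growth of the animals between these times is a biological explanation, and it was not tested here. A moult was not tested either: the furrow collagens dpy-2, dpy-3, dpy-7, dpy-8, dpy-9 and dpy-10 (shared probe) changed by 1.42, 2, 1.31, 2.75, 2.17 and 0.94.

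Of 93 antimicrobial genes 32 rose and 13 fell at 27 µM after 24 h (adjusted p = 8.24e-05, adjusted p = 0.721 with an estimated correlation). Cross-hybridisation within the families is argued against as the whole source, since 26 of the 32 have a specific probe. Animals further along the course from 24 to 48 h could give this pattern, as these genes are higher at 48 h in controls. For the test the course was taken from the arrays of the lower concentration, not from the controls. It is thus a course of exposed animals, and it sets 1 slide against the other. Genes outside the list that rise along it lay 0.113 above those that fall in their median 27 µM effect. The range was -0.074 to 0.297 without 1 array, so such a shift stays open and cannot be told apart from a response to the compound.

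Of 151 collagen genes 15 fell and 8 rose at 27 µM after 48 h, and the list was not called (adjusted p = 0.104). The dimmest array, 27 µM replicate 1, is argued against as the source, since 8 were called lower without it, though 2 and 4 without control replicates 1 and 2. Animals behind along the course from 24 to 48 h would have these 15 and others that rise with time lower. Rising and falling genes were again taken from the arrays of the lower concentration, not from the controls. The difference of their medians over genes outside the list was 0.068 (-0.035 to 0.187 without 1 array). Since the sign of that difference rests on 1 array, such a lag cannot be told apart from an effect of the compound.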

How the results depend on the processing

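Leaving out cross-hybridising probes, the within-slide list tests and leaving out arrays for the overlaps were chosen after the result was seen. Over the alternatives that keep all arrays, 5534 values of named genes kept their direction and their side of the threshold, 376 lost a call, 191 gained 1 and 9 changed sign; with 1 array left out the numbers were 2546, 599, 12 and 11. For gene lists 924 were kept, 229 lost the call, 4 gained 1 and 7 changed camera's direction, which is relative to the other genes, and with 1 array left out 566, 120, 9 and 5. The sign of the median itself changed 10 and 5 times. Of the 660 results for named genes, 382 were called in the reported setting, and 2 of those changed sign in some setting. The number of lists called, 138 of 387, was 124 after quantile normalization, 168 after normexp correction, 151 with no filter, 134 with the filter on all 12 arrays, 137 with a block, 150 with a trend, 99 without cross-hybridising probes and 123 to 145 without 1 array. With an estimated correlation limma's camera called 0 lists, with 31 tests at an unadjusted p under 0.05, while fry called 94. Signal over background limits the dim genes: 20214 of 28069 genes passed the filter, and the filter on all 12 arrays kept 16008.

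With quantile normalization the genes whose 2.7 µM effect changed with time numbered 148 (89 reported). The sign of ace-1 changed, to -0.022 at 27 µM and 24 h and 0.128 at 2.7 µM and 48 h, where it was not called. The ribosomal protein list lost calls: its median went from -0.159 to 0.004 between 27 and 2.7 µM at 24 h and from 0.232 to -0.017 for the change of the 27 µM effect. With normexp correction the count was 420 at 2.7 µM and 24 h, 514 between 27 and 2.7 µM at 48 h, 174 for the change of the 2.7 µM effect and 1207 for that of the 27 µM effect, and the overlap at 24 h was 327. It turned ace-1 at 27 µM and 24 h to -0.016, ace-3 at 2.7 µM and 48 h to 0.019, and cho-1 and rgef-1 at 27 µM and 48 h to 0.086 and 0.033, and it turned camera's direction for the muscle list between 27 and 2.7 µM at 48 h, whose median went from 0.122 to 0.073. It shifted the median of all genes by 0.124 at 27 µM and 48 h, by 0.138 between 27 and 2.7 µM at 48 h and by 0.136 for the change of the 27 µM effect, where the share called higher went from 52.4 to 64.6%. The cause was not tested for any of these.

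Without the filter on dim probes more genes were tested and fewer called, except between the times in controls (20129, against 16089 reported): 59 at 2.7 µM and 24 h, 213 at 2.7 µM and 48 h, 881 at 27 µM and 48 h, 539 and 144 between 27 and 2.7 µM at 24 and 48 h, 23 and 262 for the changes of the 2.7 and 27 µM effects, and overlaps of 53 and 163 at 24 and 48 h. With the filter on all 12 arrays fewer were tested and more called, except between the times (12936): 452 at 2.7 µM and 24 h, 307 and 1234 for the changes of the 2.7 and 27 µM effects, and an overlap of 354 at 24 h. With a block for replicate number, which leaves fewer residual degrees of freedom, the counts were 161 at 2.7 µM and 24 h, 304 at 2.7 µM and 48 h, 146 between 27 and 2.7 µM at 48 h, 3 and 394 for the changes of the 2.7 and 27 µM effects, and overlaps of 132 and 226. Correlations of the replicates' deviations between groups lay between -0.085 and 0.146, so the numbers do not pair the arrays. With a trend in eBayes the counts were 588 at 2.7 µM and 24 h, 402 between 27 and 2.7 µM at 48 h, and 337 and 1248 for the changes of the 2.7 and 27 µM effects; the cause was not tested.

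A minimum of 2-fold left, by its construction, 134 genes at 2.7 µM and 793 at 27 µM at 24 h, 229 and 509 at 48 h, 389 and 145 between 27 and 2.7 µM at 24 and 48 h, 10151 between the times in controls and 458 for the change of the 27 µM effect. A separate fit per time point, which has fewer samples and is the value within a slide, called 0 at 2.7 µM and 24 h (2583 genes at an unadjusted p under 0.05 in limma), 972 at 27 µM and 24 h, 95 between 27 and 2.7 µM at 24 h, 124 and 912 at 2.7 and 27 µM at 48 h, and 107 between them; 907, 95, 106, 760 and 93 of these were the same genes as in the reported setting. Its list tests kept 19 of 20, 14 of 14, 10 of 11 and 15 of 15 calls at 2.7 µM 24 h, 27 µM 24 h, 2.7 µM 48 h and 27 µM 48 h. Without cross-hybridising probes unc-2 at 2.7 µM and 48 h was -0.21, ttn-1 at 27 µM and 48 h -0.075 and tdc-1 for the change of the 27 µM effect -0.02; the collagen list was -0.024 and -0.081 at 2.7 and 27 µM at 24 h, the histone list 0.005 between 27 and 2.7 µM at 48 h and the sperm list -0.089 between the times, since other probes or fewer members then stand for these.

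Leaving out 1 array leaves a group with 1 sample, which is assumed to vary like the other groups, and fewer samples lower the counts. The range was 38 to 153 at 2.7 µM and 1015 to 1880 at 27 µM at 24 h, 55 to 370 and 388 to 786 at 48 h, 333 to 759 and 79 to 132 between 27 and 2.7 µM at 24 and 48 h, 0 to 67 (0 with 2011 to 2123 genes at an unadjusted p under 0.05 in limma) and 173 to 514 for the changes of the 2.7 and 27 µM effects, and 24 to 170 and 51 to 243 for the overlaps at 24 and 48 h. Among acetylcholinesterase genes ace-1 ranged from -0.096 to 0.16 at 2.7 µM and -0.132 to 0.138 at 27 µM at 24 h and from -0.093 to 0.08 and -0.058 to 0.317 at 48 h; ace-2 from -0.167 to 0.235 and -0.227 to 0.175 at 24 h; ace-3 from -0.007 to 0.423 at 27 µM and 48 h. The collagen list ranged from -0.013 to 0.201 at 2.7 µM and from -0.039 to 0.229 at 27 µM at 24 h, and the glutathione S-transferase list from -0.079 to 0.184 at 27 µM and 24 h.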

Other observations

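The genes in this paragraph were named after their values were seen. At 27 µM, genes of transport, signalling and the cuticle changed in lists that camera did not call. Over all genes 11.1% were called after 24 h. Of 141 neuropeptide and insulin genes 21 rose and 12 fell after 24 h (25 and 20 adjusted over the list alone; adjusted p = 0.414). On the log2 scale nlp-34 rose by 2.75, nlp-25 by 2.08 and the insulin-like gene ins-4 by 1.92, and ins-27 fell by 0.89. Among 437 chemoreceptor genes 33 rose and 14 fell (adjusted p = 0.691), a share near that of all genes. Of these srlf-34 was higher by 4.06 at 24 h and by 1.62 at 48 h. For ABC transporter genes 8 rose and 6 fell of 46 (adjusted p = 0.66), with pgp-14 higher by 1.85 at 24 h and 2.02 at 48 h and mrp-2 by 1.18 and 0.54. The dehydrogenase gene dhs-23 was higher by 1.37 at 2.7 µM and by 2.94 at 27 µM after 24 h. Nuclear hormone receptor genes had 14 higher and 24 lower of 217 (adjusted p = 0.0586), with nhr-178 higher by 1.87 at 24 h and 1.35 at 48 h. C-type lectin genes had 15 higher and 17 lower of 159 at 24 h (adjusted p = 0.597), with clec-70 higher by 2.70 and clec-55 lower by 2.19. The lipase gene lipl-3 was lower by 2.19 and the collagen genes col-124, col-19 and col-20 were lower by 1.69, 1.52 and 1.51 after 24 h, when 8 collagen genes rose and 15 fell (adjusted p = 0.682).

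Some lists were called with few or no members called. Hypoxia and hydrogen sulfide genes were lower in the other comparisons with a control too. Their median log2 change was -0.142 at 2.7 µM and 24 h (adjusted p = 0.0248, adjusted p = 0.721 with an estimated correlation). It was -0.334 at 2.7 µM and 48 h (adjusted p = 0.00482, adjusted p = 0.654 with an estimated correlation) and -0.26 at 27 µM and 48 h (adjusted p = 0.0212, adjusted p = 0.721 with an estimated correlation). Each of these calls was lost without 1 array, with medians of -0.019, -0.2 and -0.301 (adjusted p = 0.312, 0.191 and 0.0841). Without shared probes those at 2.7 µM and 24 h and at 27 µM and 48 h were lost, with medians of -0.045 and -0.331 (adjusted p = 0.217 and 0.0911). Pan-neuronal genes had medians of -0.103 and -0.152 at 2.7 and 27 µM after 24 h (adjusted p = 0.00753 and 0.00855, adjusted p = 0.614 with an estimated correlation for each). Without shared probes neither was called (adjusted p = 0.233 and 0.0897), with medians of -0.107 and -0.202. Ribosomal protein genes had medians of 0.184 at 2.7 µM and 24 h and 0.251 at 27 µM and 48 h, with 0 of 78 genes called in limma or adjusted over the list alone (adjusted p = 5.29e-08, adjusted p = 0.737 with an estimated correlation for each). The second was not called after quantile normalization (median 0.036, adjusted p = 0.255) or without 27 µM replicate 1 (0.07, adjusted p = 0.0568). In the controls 313 of 437 chemoreceptor genes were higher at 48 h and 23 lower (adjusted p = 5.65e-05, adjusted p = 0.597 with an estimated correlation). The 5054 dimmest genes had a median change of 1.61 between the times, 0.36 after quantile normalization, and the 5054 brightest 0.21.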
